A study of Mus musculus with 20 samples.

How the data were processed

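Poly(A)-selected, stranded RNA sequencing libraries were made from microdissected PVT and pIC punches of mice given vehicle or STZ, with 4 control and 6 STZ libraries for each region. The deposited table gave raw counts for 57180 Ensembl gene identifiers in 20 libraries, 1 column for each library and none pooled, and 24926 identifiers had no count in any library. The values were checked to be whole numbers of at least 0 with column totals that differ. The submitters' processing notes name the genome build GRCm39 (mm39). The aligner, the counting program, its strand setting and the annotation release are not given in the sources used here. Counts of near-identical genes (the Gbp and Tgtp families, Ifit3 and Ifit3b, the alpha-globin genes, class I histocompatibility genes) depend on how reads matching several places were treated, so their values are uncertain. The annotation at hand was of another build, so it served only to match 51884 identifiers to symbols, and no gene positions are given.

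Total counts were 17.9 M to 25.5 M for each library. No 2 libraries of the same group were duplicates, since the lowest replicate chi-square per degree of freedom between pairs within a group was 4.00. Pairs across groups were not compared. Intervals and errors cover the spread between libraries of a group. Groups were taken from the labels. Libraries were numbered within groups, and equal numbers in control and STZ mice were taken as different animals.

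Main tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Each region was fitted alone in edgeR 4.0.16 under R 4.3.3, with TMM scaling, filterByExpr (minimum count 10, minimum total 15) and the robust quasi-likelihood test of STZ against control. Adjusted p is the Benjamini-Hochberg value, with calls under 0.05. The difference between regions in the STZ effect was the interaction of region and treatment over all 20 libraries. PVT and pIC of control mice were compared with glmTreat against a minimum fold of 2. Fold changes of genes tested in both regions were correlated across genes. The mean and SD of CPM are over the libraries of a group, and SE is that of the log2 fold change.

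Of 1181 genes in 49 lists, 1160 had an identifier in the table, and 19 lists held markers of cell types or neighbouring regions. Lists with 5 or more tested genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Fry tests whether a list's genes move on balance in 1 direction and does not compare the list with other genes. A list score is the mean log2 CPM of its genes, and the 38 differences in marker scores (19 lists in each of 2 regions) were tested by exact permutation over 210 splits, two-sided, for which the smallest p is 0.00476. In 6 PVT and 7 pIC lists, none called, the median, the mean and the test differed in sign.

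Genes named in the text followed a rule. For each region these were, among genes with an adjusted p under 0.05, a mean of at least 1 CPM and an established symbol, the 8 higher and 8 lower with the smallest p and the 4 higher and 4 lower with the largest change. Up to 4 called members of each list by smallest p (or the 1 or 2 of smallest p where none passed) were added. For the interaction these were 3 of each sign when none passed, and for the regions 5 higher, 5 lower and members of the thalamus, PVT and cortical lists. The text gives the part of these that bears on each comparison. Genes of antigen presentation, interferon receptors, growth hormone and other pituitary and hypothalamic transcripts were named after their values were seen.

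The methods were tested on simulated data of the same design. In PVT, 53%, 71.9% and 96.8% of genes changed by 1.5, 2 and 4 fold were recovered, and in pIC 70.8%, 82.1% and 96.8%. For the interaction 34.3%, 64.2% and 86.2% were recovered at the same folds, and for the regions 0%, 86.4% and 95.4% at 2, 4 and 8 fold, the first by construction. Unchanged genes were 5.37%, 6.4%, 3.94% and 0% of the calls. A list shifted by 1.5 fold was called in each region by camera with either correlation and by fry, with 0 of the unshifted lists called. The counts of each simulated gene were drawn independently of other genes. The simulation therefore did not test false calls of genes that vary together, as with punch content, or of lists of such genes. Its shares of unchanged genes among the calls do not cover that case.

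Alternatives were RLE (DESeq2 size factors) and upper quartile scaling, DESeq2 1.42.0, limma-voom with quality weights, other filters and thresholds, and list scores as covariates. Others were a block (the replicate number within a region, the label across regions), all libraries in 1 fit and leaving out each library. Data on behaviour, blood glucose and sex of the mice are not given in the sources used here. No library was left out of the main tests.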

Results

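Gene expression was measured by poly(A) RNA sequencing in tissue punches from 2 brain regions of mice with painful diabetic neuropathy and of vehicle-treated mice. Diabetes was induced with 1 injection of 200 mg/kg streptozotocin (STZ), a toxin taken up by pancreatic beta cells, and tissue was taken at week 7. The paraventricular thalamic nucleus (PVT) is a midline thalamic relay for arousal and aversion, and the posterior insular cortex (pIC) processes pain and body state. There were 4 control and 6 STZ libraries for each region, 20 in all. Total counts were 17.9 M to 24.5 M in PVT control, 21.7 M to 25.3 M in PVT STZ, 21.2 M to 23.3 M in pIC control and 19 M to 25.5 M in pIC STZ libraries. Mitochondrially encoded genes took 5.57% to 7.01% of the counts of a library.

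The comparison of PVT with pIC in control mice (n = 4 libraries each) described what each dissection contained. Zic1 (ENSMUSG00000032368), a zinc-finger transcription factor, was higher in PVT by 4.32 on the log2 scale (207 ± 36.5 CPM against 10.4 ± 1.32, mean ± SD, adjusted p = 2.5e-07). Prkcd (ENSMUSG00000021948), a protein kinase C that marks thalamic neurons, was higher by 3.52 (adjusted p = 2.5e-07), and Calb2 (ENSMUSG00000003657), the calcium buffer calretinin of midline thalamic neurons, by 4.07 (adjusted p = 6.4e-04). Kcne2 (ENSMUSG00000039672), a potassium channel subunit of choroid plexus, was higher by 8.53 (adjusted p = 7.2e-08), and Cldn2 (ENSMUSG00000047230), a choroid plexus tight-junction protein, by 8.45 (adjusted p = 1.2e-06). Cux2 (ENSMUSG00000042589), a transcription factor of upper cortical layers, was lower in PVT with a log2 difference of −1.46 (28.8 ± 3.0 against 79.3 ± 3.0 CPM, adjusted p = 5.4e-04). In STZ mice the adjusted p for Cux2 was 1, and over all its alternatives it ran from 8.1e-07 to 1.

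Against a minimum fold of 2, 781 genes were higher and 92 lower in PVT among 16614 tested (edgeR). The choroid plexus list had 17 of 18 members higher in PVT (median 6.15), the ependyma list 15 of 16 (median 3.74), the PVT neuron list 6 of 15 and the thalamus neuron list 4 of 16, while 1 of 16 cortical excitatory genes was lower. Tcf7l2, a thalamic transcription factor, had a log2 difference of 3.48 with an adjusted p of 0.0554, and Slc17a7, the cortical vesicular glutamate transporter, −2.24 with 0.35. Their SDs in PVT libraries were 30.5 CPM on a mean of 42.0 for Tcf7l2 and 249 on a mean of 334 for Slc17a7. The lower genes numbered 27 without control replicate 1, 224 without control replicate 2 and 44 without control replicate 4.

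Scores of 19 cell type and region lists (mean log2 CPM) described how the punches varied. In PVT libraries the thalamus score spanned 4.39-fold, the striatal score 10.3-fold and the hypothalamus score 12.9-fold, and the striatal score spanned 11.4-fold in pIC libraries. None of the 38 differences between STZ and control passed adjustment (exact permutation test, two-sided, smallest possible p 0.00476, lowest adjusted p 0.0905), while 6 had an unadjusted p under 0.05. The ependyma score in PVT had a difference of −0.68 (exact p = 0.00476, adjusted p = 0.0905), and the endothelium score in pIC −0.26 with the same exact and adjusted p. Both had the smallest possible p, so a list could pass only along with more lists of low p. The lack of calls therefore does not show equal content. For oligodendrocytes and myelin in PVT the difference was −0.36 (exact permutation p = 0.00952, adjusted p = 0.121), and for choroid plexus in PVT −0.74 (exact p = 0.0381, adjusted p = 0.29). PVT control replicate 4 also held growth hormone (Gh) at 12500 CPM and prolactin (Prl) at 2220 CPM, against at most 1.54 CPM and 0.385 CPM in the other PVT control libraries.

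**Figure D1:**
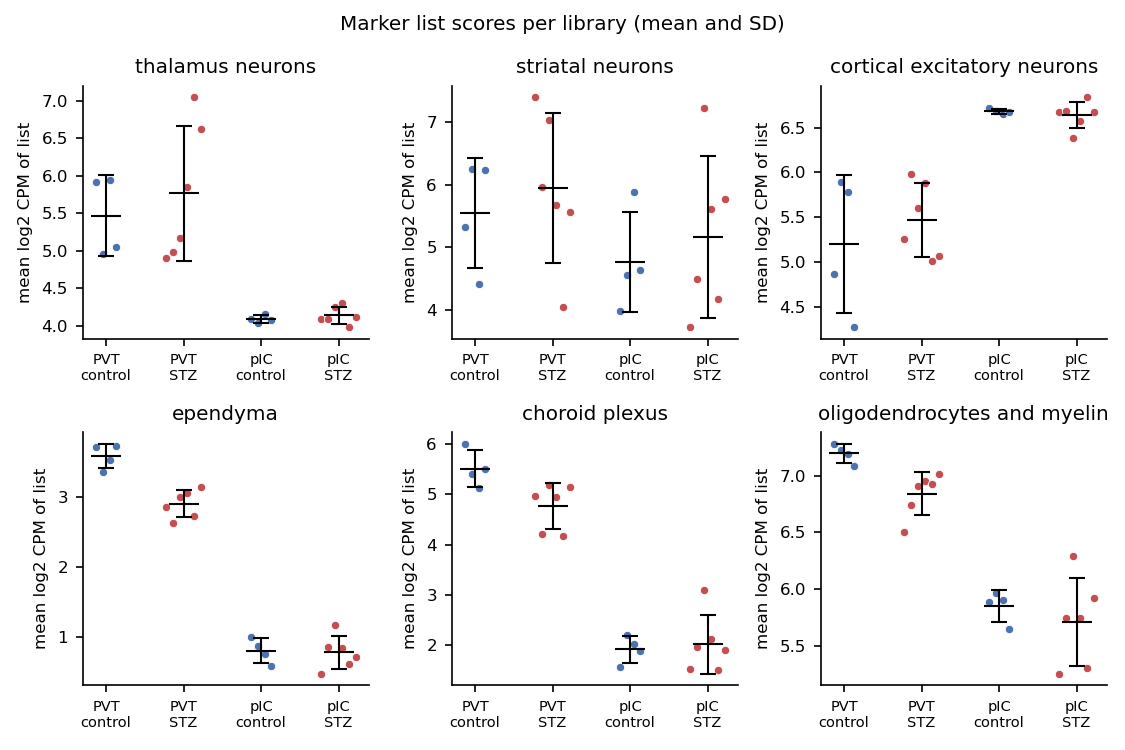
Mean log2 CPM of 6 marker lists (vertical axes) in each library of the 4 groups, with group mean and SD. Thalamus and striatal scores spread over 4.39-fold and 10.3-fold among PVT libraries of both treatments, and ependyma scores had means of 3.58 in PVT control and 2.90 in PVT STZ libraries.

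In the PVT, the comparison of STZ with control mice asked which genes differ in diabetic mice with neuropathy (n = 4 control and 6 STZ libraries). Of 27 measured genes of the interferon list 26 were lower. Lgals3bp (ENSMUSG00000033880), a secreted glycoprotein induced by interferons, fell by 2.17 on the log2 scale (SE 0.108, adjusted p = 2.2e-06), from 101 ± 17.6 to 22.5 ± 2.03 CPM (mean ± SD), and Gbp3 (ENSMUSG00000028268), an interferon-inducible GTPase, by 2.15 (SE 0.106, adjusted p = 2.2e-06). Rtp4 fell by 2.64 (SE 0.193, adjusted p = 4.6e-05), Usp18, which removes ISG15 and restrains interferon receptor signalling, by 2.41 (SE 0.206, adjusted p = 1.4e-04), and Ifi27l2a by 3.60 (SE 0.242, adjusted p = 2.9e-05). The remaining gene of the list did not pass over all genes, and 27 were lower when adjusted over the list alone. The list's median was −1.66 (camera, adjusted p = 3.7e-49). Its adjusted p was 0.0126 with an estimated correlation, the highest of its alternatives, the lowest being 5.6e-54.

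**Figure D2:**
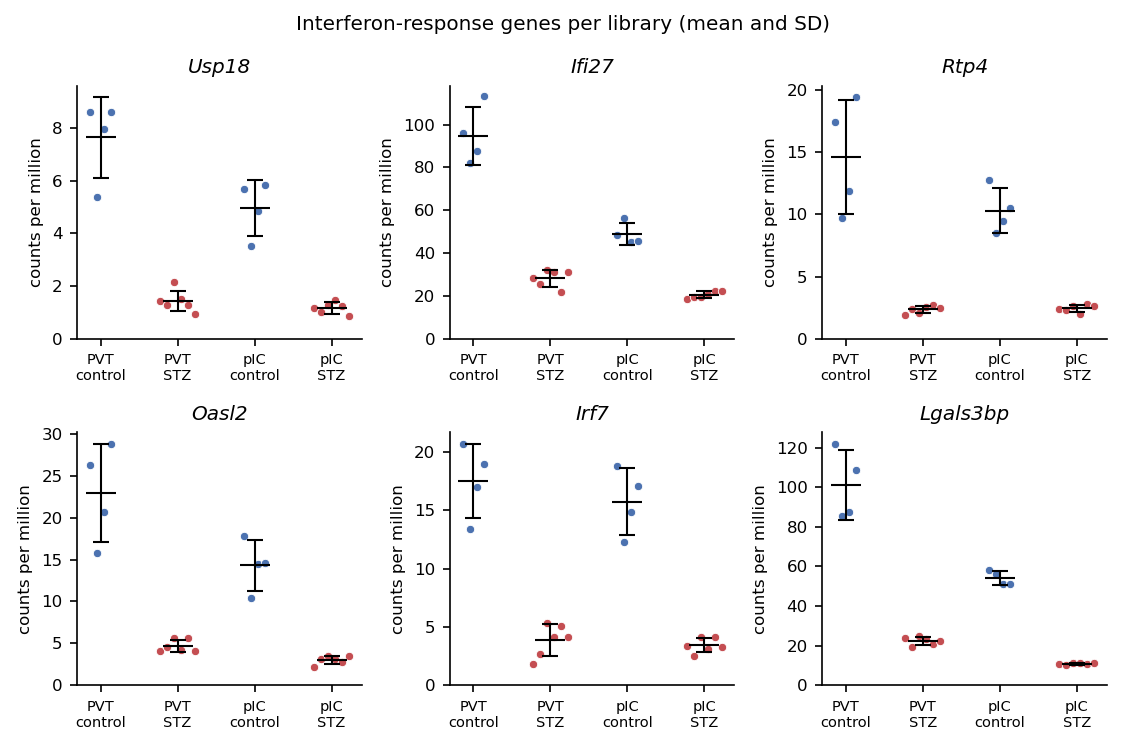
CPM (counts scaled to library size, vertical axes) of 6 interferon-response genes in each library of the 4 groups, with group mean and SD. Lgals3bp lay at 85.6 to 122 CPM in PVT control and 19.4 to 25 in PVT STZ libraries, and at 50.9 to 58.5 and 9.89 to 11.1 CPM in the pIC.

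Of 34 genes induced by glucocorticoids 12 were higher and 0 lower in the PVT of STZ mice. Plin4 (ENSMUSG00000002831), a lipid droplet coat protein, rose by 2.05 on the log2 scale (SE 0.235, adjusted p = 0.00143), from 15.3 ± 5.65 to 63.5 ± 8.12 CPM. Sult1a1, a sulfotransferase, rose by 0.92 (SE 0.127, adjusted p = 0.0038), Arrdc2 by 0.98 (SE 0.139, adjusted p = 0.00433), Nfkbia, the inhibitor of NF-kB, by 0.92 (SE 0.139, adjusted p = 0.00729) and Ddit4, an inhibitor of mTORC1, by 0.54 (SE 0.068, adjusted p = 0.00188). The glucocorticoid list had 18 higher when adjusted over the list alone and a median of 0.41 (camera, adjusted p = 6.5e-14). Its call was lost at adjusted p = 0.0841 with an estimated correlation, and its alternatives ran from 8.2e-16 to 0.0841. Outside this list, Mfsd2a (ENSMUSG00000028655), the transporter of lysophosphatidylcholine-bound docosahexaenoic acid at the blood-brain barrier, rose by 0.98 (SE 0.0814, adjusted p = 1.1e-04). The secreted serine protease Htra1 (ENSMUSG00000006205) rose by 0.68 (SE 0.0788, adjusted p = 9.4e-04), and sulfiredoxin, Srxn1, which repairs oxidised peroxiredoxins, by 0.55 (SE 0.0701, adjusted p = 0.002). A fit without the 4 PVT libraries lowest in thalamus genes lacked control replicates 2 and 4 and STZ replicates 1 and 2. Its fewer libraries alone may raise p. In it the adjusted p was 0.207 for Arrdc2, 0.367 for Nfkbia, 0.19 for Ddit4, 0.139 for Htra1 and 0.197 for Srxn1. These were the highest of their alternatives, whose lowest were 1.6e-08, 1.4e-07, 1.8e-10, 6.7e-14 and 2.0e-10. For Sult1a1 the adjusted p was 0.108 in that fit and 0.161 with the choroid plexus score, the highest of its alternatives, whose lowest was 6.1e-09.

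**Figure D3:**
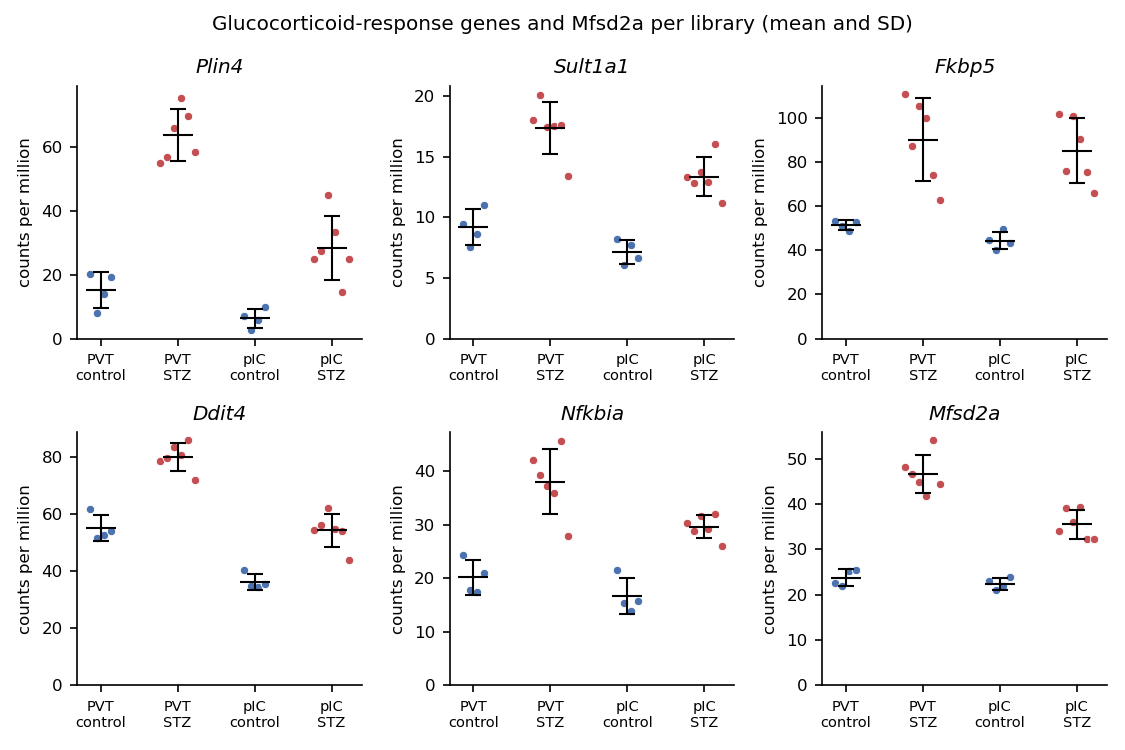
CPM (counts scaled to library size, vertical axes) of 5 genes of the glucocorticoid list and of Mfsd2a in each library of the 4 groups, with group mean and SD. Plin4 lay at 7.86 to 20.2 CPM in PVT control and 54.8 to 75.3 in PVT STZ libraries, and at 2.56 to 9.94 and 14.5 to 44.8 CPM in the pIC.

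Of 16 genes of ciliated ependymal cells, which line the ventricles, 12 were lower in the PVT of STZ mice. Rarres2 (ENSMUSG00000009281), the secreted protein chemerin, fell by 0.75 (SE 0.103, adjusted p = 0.00371), and Tmem212, an ependymal membrane protein, by 0.72 (SE 0.113, adjusted p = 0.00862). The ependyma list had 16 lower when adjusted over the list alone and a median of −0.71 (camera, adjusted p = 1.6e-16, adjusted p = 0.244 with an estimated correlation). None of the 18 choroid plexus genes passed over all genes, 9 were lower when adjusted over the list alone, and the median was −0.73 (camera, adjusted p = 7.7e-08, adjusted p = 0.448 with an estimated correlation). The adjusted p of these lists ran from 5.6e-18 to 0.775 for ependyma and from 7.5e-19 to 0.448 for choroid plexus over their alternatives. The 0.775 came with the ependyma score itself as a covariate, a score that did not overlap between the groups. In that fit the choroid plexus median turned to 0.47 and the list was called in the opposite direction (camera, adjusted p = 1.7e-04). Of 22 myelin genes 6 were lower, 15 were lower when adjusted over the list alone, and the list had a median of −0.34 (camera, adjusted p = 1.2e-10, adjusted p = 0.432 with an estimated correlation, alternatives 6.8e-14 to 0.432). Mog (ENSMUSG00000076439), a myelin surface protein, fell by 0.52 (SE 0.0797, adjusted p = 0.00745), and Opalin, an oligodendrocyte membrane protein, by 1.16 (SE 0.174, adjusted p = 0.00772). With the choroid plexus score in the model the adjusted p was 0.168 for Rarres2, 0.3 for Tmem212, 0.234 for Mog and 0.239 for Opalin. The lowest among their alternatives was 5.3e-08 for Rarres2, 2.4e-06 for Tmem212, 2.2e-06 for Mog and 9.1e-08 for Opalin, and the highest 0.168, 0.319, 0.234 and 0.303.

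Neuronal lists had small positive medians in the PVT with few or no single genes past the test. Marker lists of the neurons in a punch had positive medians too, 0.62 for striatal, 0.46 for thalamus and 0.18 for cortical excitatory neurons. None of these was called (camera, adjusted p = 0.14, 0.16 and 0.14). The medians below are therefore not to be read apart from punch content. The ion channels of neuronal excitability had a median of 0.22 with 0 of 54 members called by edgeR over all genes and 0 when adjusted over the list alone (camera, adjusted p = 1.9e-06, adjusted p = 0.359 with an estimated correlation, alternatives 4.9e-07 to 0.587). Postsynaptic scaffold and adhesion genes had a median of 0.25 with 0 of 30 called and 3 when adjusted over the list alone (camera, adjusted p = 4.3e-06, adjusted p = 0.448 with an estimated correlation). Their scaffold members Shank3 and Dlgap3 had log2 fold changes of 0.49 and 0.61 with adjusted p of 0.0596 and 0.061, which became 0.0389 and 0.00947 without control replicate 2, within ranges of 0.00454 to 0.555 and 0.00287 to 0.539 over their alternatives. For the synaptic vesicle list the median was 0.16 with 1 of 31 called, both over all genes and when adjusted over the list alone (camera, adjusted p = 7.7e-04, adjusted p = 0.629 with an estimated correlation, and 0.128 without control replicate 4). Glutamate receptors had a median of 0.12 with 1 of 24 called and 2 when adjusted over the list alone (camera, adjusted p = 0.00514, adjusted p = 0.359 with an estimated correlation, and 0.0596 without control replicate 4). GABA and glycine receptors had a median of 0.14 with 0 of 19 called and 0 when adjusted over the list alone (camera, adjusted p = 0.009, adjusted p = 0.448 with an estimated correlation, and 0.0598 without control replicate 4). The called members were Rims2, an active zone protein, with 0.34 (SE 0.073, adjusted p = 0.042), and the NMDA receptor subunit Grin2c with 0.52 (SE 0.0909, adjusted p = 0.0166). Without control replicate 4 their adjusted p became 0.0918 and 0.0618, within ranges of 0.00196 to 0.487 and 4.9e-05 to 0.382 over their alternatives. The adjusted p over alternatives ran from 7.0e-09 to 0.448 for the postsynaptic, 1.6e-05 to 0.629 for the vesicle, 0.00271 to 0.525 for the glutamate receptor and 0.00268 to 0.448 for the GABA and glycine receptor list. With the ependyma score in the model the medians were −0.12 for postsynaptic and −0.15 for synaptic vesicle genes. That score did not overlap between the groups, so fits with it cannot separate its part from that of STZ. Immediate early genes had a median of −0.09 in the PVT, 0 of 32 called and 0 when adjusted over the list alone (camera, adjusted p = 0.607). That median was −0.20 to 0.01 with 1 library left out, and −0.70 with the ependyma score in the model, where the list was called (adjusted p = 1.6e-05).

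The metabolic, reactive astrocyte and ribosomal lists called in the PVT had medians of −0.21 to 0.05. Cholesterol synthesis genes had a median of −0.20, with 1 of 27 lower and 12 lower when adjusted over the list alone (camera, adjusted p = 4.9e-06, adjusted p = 0.367 with an estimated correlation, alternatives 1.6e-10 to 0.367). The called gene was Insig1, a sterol-sensing regulator, which fell by 0.50 (SE 0.0933, adjusted p = 0.0232) and had an adjusted p of 0.0759 without control replicate 1 and up to 0.321 with the choroid plexus score. Fatty acid oxidation genes had a median of −0.11, with 3 of 32 lower, and 9 lower and 1 higher when adjusted over the list alone (camera, adjusted p = 9.3e-04, adjusted p = 0.294 with an estimated correlation, alternatives 8.45e-04 to 0.294). Glycolysis and glucose transport had a median of 0.05 with 1 of 31 called, and 1 when adjusted over the list alone (camera, adjusted p = 0.0275, adjusted p = 0.569 with an estimated correlation). The called gene was Slc2a1, the glucose transporter GLUT1, with 0.45 (SE 0.0788, adjusted p = 0.0173, 0.061 without control replicate 4, alternatives 2.1e-05 to 0.375). Reactive astrocyte genes had a median of −0.21 with 5 of 19 lower, and 3 higher and 6 lower when adjusted over the list alone (camera, adjusted p = 0.0138, adjusted p = 0.244 with an estimated correlation, 0.0668 without control replicate 1 and 0.0598 without control replicate 4, alternatives 0.00414 to 0.244). Complement C3 fell by 1.03 (SE 0.169, adjusted p = 0.0109) and H2-D1, a class I histocompatibility gene with near-identical relatives, by 0.90 (SE 0.11, adjusted p = 0.0015). The adjusted p was 0.326 for C3 with the choroid plexus score and 0.124 for H2-D1 without the 4 libraries lowest in thalamus genes, the highest of their alternatives, whose lowest were 7.9e-06 and 3.2e-10. H2-D1 is also among the class I presentation genes given below, of which 11 of 13 were lower in the PVT. The fall of the astrocyte list was not separated from theirs. In the pIC the astrocyte list had a median of 0.226, with 1 of 18 higher and 2 lower (camera, adjusted p = 0.23). Ribosomal protein genes had a median of −0.06, with 0 of 76 called and 0 when adjusted over the list alone (camera, adjusted p = 0.042, adjusted p = 0.807 with an estimated correlation).

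Over all genes in the PVT, 353 of 17076 tested passed (edgeR, 81 higher and 272 lower), with 10 higher and 95 lower by 2-fold or more. In 347 of them the groups did not overlap. With upper quartile scaling 58 genes were higher and 416 lower. Leaving out 1 library gave 156 (without control replicate 1), 211 (without control replicate 3), 143 (without control replicate 4), 210 (without STZ replicate 1), 206 (without STZ replicate 3) or 151 genes (without STZ replicate 4). It gave 315 without control replicate 2, 242 without STZ replicate 2, 236 without STZ replicate 5 and 343 without STZ replicate 6. DESeq2 called 904 genes, the model with the thalamus score 1175, the model with the choroid plexus score 50 and a fit of all 20 libraries 679. The fit without the 4 libraries lowest in thalamus genes, with fewer libraries in both groups, called 35.

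In the pIC, the comparison of STZ with control mice asked the same question of the cortex (n = 4 control and 6 STZ libraries), and 25 of 27 genes of the interferon list were lower there. Lgals3bp (ENSMUSG00000033880) fell by 2.33 on the log2 scale (SE 0.0615, adjusted p = 4.9e-11), from 54.2 ± 3.66 to 10.8 ± 0.473 CPM. Gbp3 fell by 2.02 (SE 0.11, adjusted p = 4.0e-07), and Irf7 (ENSMUSG00000025498), the transcription factor that amplifies type I interferon production, by 2.20 (SE 0.147, adjusted p = 1.6e-06). Oasl2, an interferon-induced relative of the oligoadenylate synthetases, fell by 2.26 (SE 0.151, adjusted p = 1.6e-06). The interferon list had 27 lower when adjusted over the list alone and a median of −1.38 (camera, adjusted p = 2.2e-61). It kept an adjusted p of 0.00461 with an estimated correlation, the highest of its alternatives, the lowest being 3.1e-71.

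Of 34 glucocorticoid-induced genes 11 were higher in the pIC of STZ mice. Fkbp5 (ENSMUSG00000024222), a co-chaperone of the glucocorticoid receptor, rose by 0.94 (SE 0.124, adjusted p = 0.00218), from 44.3 ± 3.87 to 85.0 ± 14.7 CPM. Sult1a1 rose by 0.90 (SE 0.113, adjusted p = 6.9e-04), Nfkbia by 0.83 (SE 0.109, adjusted p = 0.00108) and Ddit4 by 0.58 (SE 0.0844, adjusted p = 0.00218). Plin4 had a log2 fold change of 2.16 (SE 0.404, adjusted p = 0.0402), with an adjusted p of 0.119 without control replicate 1 and 0.0702 without control replicate 2, and 1.0e-05 by DESeq2. The list had 23 higher and 1 lower when adjusted over the list alone, and a median of 0.35 (camera, adjusted p = 1.1e-17). Its adjusted p = 0.192 with an estimated correlation, and its alternatives ran from 1.8e-22 to 0.192. Smox, spermine oxidase, rose by 0.53 (SE 0.0508, adjusted p = 5.9e-05), Mfsd2a by 0.67 (SE 0.075, adjusted p = 2.4e-04), Htra1 by 0.37 (SE 0.0498, adjusted p = 0.00149) and the phosphatase regulator Ppp1r10 by 0.60 (SE 0.0613, adjusted p = 1.0e-04).

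Of 32 immediate early genes, which neurons switch on with activity, 7 were lower in the pIC. Klf10 (ENSMUSG00000037465) fell by 1.00 (SE 0.117, adjusted p = 8.1e-04), from 73.0 ± 7.16 to 36.5 ± 6.56 CPM, and Gadd45b by 0.47 (SE 0.077, adjusted p = 0.00561). Egr1 fell by 0.76 (SE 0.124, adjusted p = 0.0103, and 0.0557 without control replicate 2). The list had 19 lower when adjusted over the list alone and a median of −0.51 (camera, adjusted p = 4.5e-17, adjusted p = 0.192 with an estimated correlation, alternatives 4.4e-20 to 0.192). In a fit of all 20 libraries the adjusted p was 0.178 for Klf10, 0.211 for Gadd45b and 0.473 for Egr1, the highest of each gene's alternatives, whose lowest were 2.3e-13, 1.1e-05 and 1.7e-07.

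Of 27 cholesterol synthesis genes 10 were lower in the pIC. Insig1 (ENSMUSG00000045294) fell by 0.68 (SE 0.102, adjusted p = 0.00439), and Sqle, squalene epoxidase, by 0.41 (SE 0.0663, adjusted p = 0.00548). The list had 19 lower and 1 higher when adjusted over the list alone, and a median of −0.27 (camera, adjusted p = 1.2e-14, adjusted p = 0.192 with an estimated correlation, alternatives 5.1e-16 to 0.192). Of 18 endothelial genes 3 were lower, 8 were lower when adjusted over the list alone, and the list had a median of −0.22 (camera, adjusted p = 4.2e-06, adjusted p = 0.192 with an estimated correlation, alternatives 5.5e-08 to 0.192). Among them the endothelial transcription factor Sox18 fell by 0.68 (SE 0.121, adjusted p = 0.0111) and Itm2a by 0.49 (SE 0.0698, adjusted p = 0.00218). Blood cell genes had a median of 0.51, with 0 of 6 called by edgeR over all genes and 2 higher when adjusted over the list alone (camera, adjusted p = 0.00346, adjusted p = 0.817 with an estimated correlation, alternatives 4.3e-05 to 0.817). In the PVT the blood cell median was 0.42, with 0 of 7 called and 0 when adjusted over the list alone (camera, adjusted p = 0.0296, adjusted p = 0.64 with an estimated correlation, alternatives 0.00455 to 0.667). That call was lost without control replicate 1 (0.155), control replicate 4 (0.109), STZ replicate 2 (0.0731) or STZ replicate 6 (0.0849). Myelin genes had a median of −0.10 in the pIC and 0 of 22 called (camera, adjusted p = 0.225), and ependymal genes −0.02 with 1 of 10 lower (camera, adjusted p = 0.609). The myelin list was called in the pIC without STZ replicate 3 (median −0.245, adjusted p = 5.2e-04) and with the striatal score in the model (−0.25, adjusted p = 1.6e-04), and the ependymal median ran from −0.18 to 0.04 with 1 library left out.

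Over all genes in the pIC, 226 of 16189 tested passed (edgeR, 70 higher and 156 lower), with 10 higher and 62 lower by 2-fold or more. In 220 of them the groups did not overlap. The count was 133 without control replicate 1, 128 without control replicate 2 and 139 without control replicate 4. Leaving out any other single library gave 158 (without STZ replicate 4) to 272 genes (without STZ replicate 3). DESeq2 called 468 genes, limma-voom 367 and the model with the striatal score 375. Camera called 16 of 49 lists in the PVT and 6 in the pIC, and the interferon list was the 1 list in each tissue that kept its call with an estimated correlation.

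**Figure D4:**
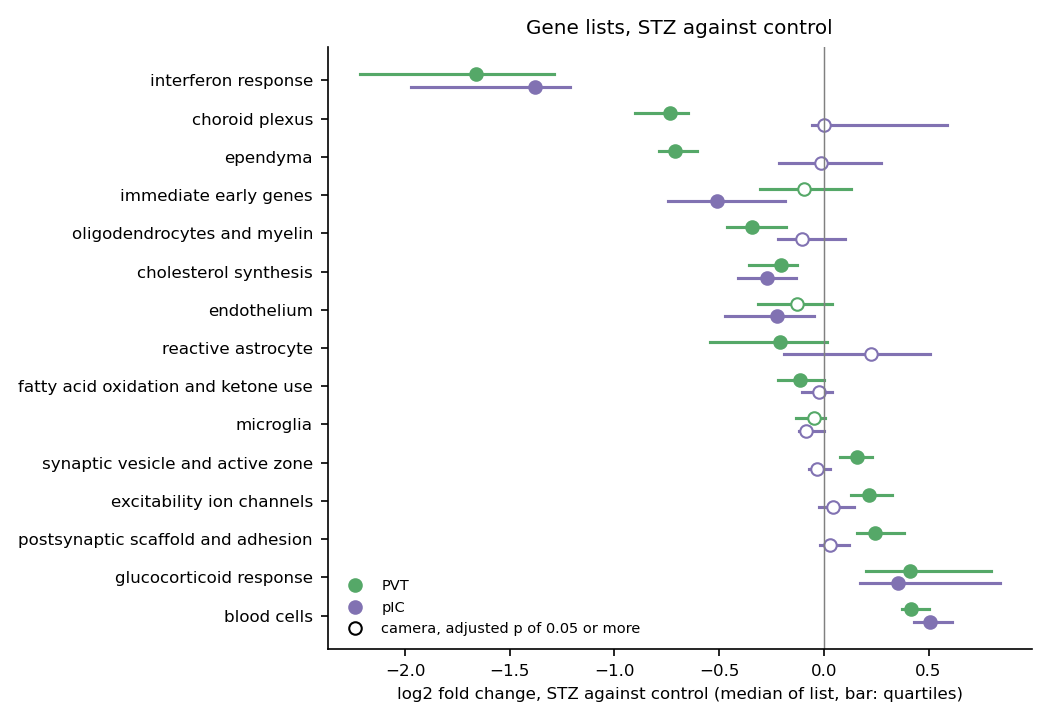
Median log2 fold change (STZ against control, horizontal axis) of 15 gene lists in PVT and pIC, with bars from the lower to the upper quartile of each list's genes and open circles where the camera adjusted p was 0.05 or more. The interferon list lay at −1.66 in PVT and −1.38 in pIC, and the glucocorticoid list at 0.41 and 0.35.

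The comparison of the STZ effect between regions asked whether thalamus and cortex differ in their response. Genes called in both regions moved in the same direction. There were 23 higher in both (0.351 expected if the calls were independent) and 90 lower in both (2.30 expected), with 0 in opposite directions among 15975 genes tested in both. Whether PVT and pIC libraries with the same label came from the same mouse is not given in the sources used here, and neither the expected numbers nor the test of the difference takes such sharing into account. Of the 90 lower genes, 25 belonged to the interferon list. That list did not hold every interferon-induced gene, since 0 of 15 interferon-induced GTPases, Gbp3 among them, belonged to it. Mfsd2a, Htra1, Ppp1r10, Sult1a1 and Nfkbia were among the genes that passed upward in both regions, and Lgals3bp, Gbp3 and Rtp4 among those that passed downward. For Ppp1r10 the adjusted p in the PVT was 0.139 without the 4 libraries lowest in thalamus genes. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.517 and a Spearman rho of 0.451. Without the interferon list, and with other interferon-induced genes kept, these were 0.483 and 0.448. The Spearman value was 0.283 without control replicate 2.

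**Figure D5:**
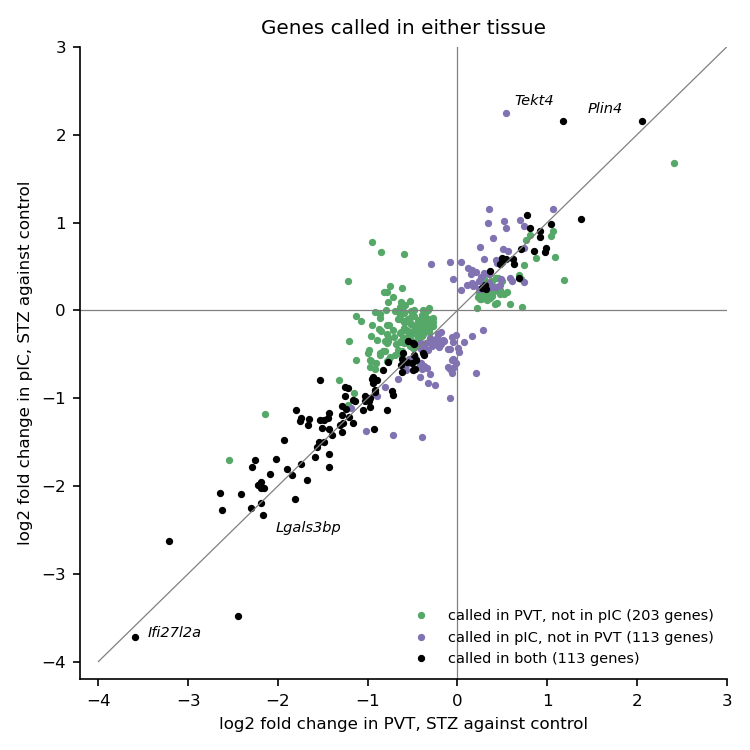
Log2 fold change (STZ against control) in PVT (horizontal axis) and pIC (vertical axis) for genes tested in both regions and called in at least 1. Colour shows where a gene was called, and genes called in neither region are not drawn. Genes called in both (113) lie in the lower left and upper right, with 90 lower and 23 higher in both regions and 0 in opposite directions.

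A test of the difference itself called 0 of 17427 genes (edgeR, interaction of region and treatment), with 701 at an unadjusted p under 0.05, while DESeq2 called 4. Rarres2 (ENSMUSG00000009281) had a PVT minus pIC difference of −1.04 (SE 0.165, adjusted p = 0.0679), with effects of −0.75 in PVT and 0.28 in pIC. Its adjusted p was 4.3e-04 by DESeq2, 0.0471 without control replicate 2, 0.0154 without STZ replicate 1 and 0.921 without control replicate 4, the range over its alternatives. Lbp, lipopolysaccharide-binding protein, had a difference of −1.75 (SE 0.314, adjusted p = 0.168, DESeq2 3.2e-04, 0.0435 without control replicate 3 and 1 without control replicate 1 or 4). Tekt4, a cilia tektin, had −1.72 (SE 0.335, adjusted p = 0.216, DESeq2 0.0209, up to 1 without control replicate 1 or 4), and 2410004P03Rik, chosen after its values were seen, −1.52 (SE 0.282, adjusted p = 0.168, DESeq2 0.0209). In the fits of each region alone, Tekt4 was called in the pIC (edgeR, adjusted p = 4.0e-04) and not in the PVT. The largest positive differences by p were Srxn1 (0.33), Fstl4 (0.67) and Cdk5r1 (0.36), each with an adjusted p of 0.767.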

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

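The tests of microglia, endothelium, ventricular wall and cortical share below, the fits with the thalamus, striatal, cortical or ependyma scores as covariates, and the pituitary and hypothalamic markers were chosen after the data were seen, and the others before.

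Of 27 interferon-response genes 26 were lower in the PVT of STZ mice and 25 in the pIC. Fewer microglia would lower their markers too, but the lower of the list's medians in PVT and pIC was −0.0861, and for endothelial cells it was −0.223, against interferon medians of −1.66 and −1.38, so loss of either cell type as the whole cause was argued against. Glucocorticoids restrain interferon signalling, and 12 of 34 of their target genes were higher in PVT and 11 in pIC (adjusted p = 0.0841 and 0.192 for the list with an estimated correlation), but over the 6 STZ libraries the scores of both lists had a Pearson r of −0.0206 in pIC (exact permutation p = 0.962, two-sided, Spearman 0.0857, p = 0.919) and 0.214 in PVT (exact p = 0.679, Spearman 0.0857, p = 0.919). Without the 2 farthest libraries r was 0.818 and 0.985 on 4 libraries, and 3 such relations gave adjusted p of 0.962 for both, so 6 libraries left this explanation open. A lower interferon tone in diabetic mice remains among the open explanations as a hypothesis, since it was found and tested on these data, and differences in housing or microbial exposure between the groups were not tested.

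In the STZ PVT 12 of 16 ependymal and 0 of 18 choroid plexus genes passed as lower, with list medians of −0.71 and −0.73 (adjusted p = 0.244 and 0.448 with an estimated correlation), and the amount of ventricular wall in a punch is a candidate explanation. Within groups, over 10 libraries, the scores of both lists had a Pearson r of 0.792 (permutation p = 0.0164, adjusted 0.0492) and a Spearman rho of 0.673 (permutation p = 0.0585, adjusted 0.176), and r was 0.784 without the 2 farthest libraries. Shifts between thalamus, striatum and cortex were argued against, since the ependyma median was −0.867 with those 3 scores as covariates, and so was pituitary RNA in PVT control replicate 4, with a median of −0.623 without it. With the ependyma score as a covariate the choroid plexus list was called in the opposite direction (median 0.47, adjusted p = 1.7e-04), in a fit whose covariate did not overlap between the groups, so it decided nothing on a shared cause. A change in ependymal cells of diabetic mice was not tested apart from punch content and stays open.

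Of 32 immediate early genes 7 were lower in the STZ pIC (list median −0.51, adjusted p = 0.192 with an estimated correlation). A smaller share of cortical excitatory neurons was argued against by their list median of −0.0684, and striatal tissue in the punches by an immediate early median of −0.524 with the striatal score as a covariate. Lower neuronal activity before the tissue was taken, or a difference in handling or time to dissection between the groups, may each lower these genes, and neither was tested.

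Libraries that stood apart from their group were sought by the gap to the nearest other library, which chance passes in about 1 of 20 groups. Of 196 groups of list scores 11 passed (9.8 expected), of 264 groups of named genes 4 (13.2 expected), of 4 groups of total counts 0, and of 16 groups of markers chosen after the data were seen 6. In PVT control libraries the hypothalamus score was 1.01 in replicate 2 (others 3.01 to 3.33), the insulin and IGF score 5.38 in replicate 3 (5.44 to 5.45), the circadian score 5.46 in replicate 2 (5.3 to 5.32) and the glutamate receptor score 5.74 in replicate 4 (5.98 to 5.99). In PVT STZ libraries the microglia score was 4.25 in replicate 5 (4.37 to 4.43), fatty acid oxidation 4.88 in replicate 6 (4.79 to 4.82), oxidative stress 5.92 in replicate 4 (5.98 to 6) and peptide receptors of pain and stress 3.65 in replicate 2 (3.68 to 3.7). The extracellular matrix score in that group was 4.78 in replicate 5 (4.64 to 4.69). In pIC STZ libraries the endothelium score was 4.46 in replicate 6 (4.21 to 4.29) and glycolysis 6.96 in replicate 3 (7.02 to 7.04). Itm2a was 67.2 CPM in PVT control replicate 4 (56.4 to 57.5) and Lyve1 0.641 CPM in pIC control replicate 2 (0.941 to 0.989). Slc16a1, a monocarboxylate transporter, was 30.6 CPM in pIC STZ replicate 5 (21.3 to 23.9), and Lrrtm3 87.2 CPM in pIC STZ replicate 3 (66 to 72).

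Growth hormone, a pituitary transcript, was 12500 CPM in PVT control replicate 4 (others 0.0534 to 1.54) and prolactin 2220 CPM (others 0 to 0.385). The same library held Pomc at 879 CPM and Cga at 347 CPM. Growth hormone was 34 CPM in pIC control replicate 4 (0 to 0.595), 2.88 in PVT STZ replicate 2 (0 to 0.402) and 1.29 in pIC STZ replicate 2 (0.0524 to 0.233), and prolactin was 2.2 CPM in pIC control replicate 4 (others 0).

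The STZ effect on 16 lists differed between PVT and pIC by camera on the interaction, each with a preset correlation, and none kept its call with an estimated correlation (lowest adjusted p 0.0804, for ependyma). The median over a list's genes of the difference in STZ effect (PVT minus pIC) was −0.828 for ependyma, −0.741 for choroid plexus, −0.23 for oligodendrocytes and myelin, −0.218 for the interferon list and −0.219 for reactive astrocytes. It was 0.41 for immediate early genes, 0.18 for postsynaptic genes, 0.173 for synaptic vesicle genes, 0.158 for excitability channels, 0.126 for GABA and glycine receptors and 0.0669 for glutamate receptors. The remaining medians were 0.261 for cortical excitatory neurons, 0.114 for endothelium, 0.0672 for glycolysis, −0.0773 for fatty acid oxidation and −0.0839 for ribosomal proteins.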

How the results depend on the processing

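Covariates of thalamus, ependyma and 3 combined scores, the striatal score for the pIC lists, the fit without the 4 PVT libraries lowest in thalamus genes, the marker scores of the split of 883 genes and the genes outside the rule were chosen after the data were seen. The interferon list kept its direction and call in both regions under every alternative run, with medians of −1.70 to −1.35 in PVT and −1.52 to −1.31 in pIC, and the immediate early median in pIC was −0.56 to −0.46. Of 74 named genes in PVT, 68 kept their side of the threshold by DESeq2, 72 with RLE scaling, 30 with the choroid plexus score, 27 without the 4 libraries lowest in thalamus genes and 63 with all 20 libraries in 1 fit, and in pIC 58 of 58 did by DESeq2 and 48 with all 20 libraries in 1 fit. Leaving out 1 library ended the call of 26 named genes in PVT and 18 in pIC in at least 1 case.

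Against 353 in PVT, the count was 904 by DESeq2, 50 with the choroid plexus score, 1175 with the thalamus score, 35 without those 4 libraries (fewer samples), 679 with all 20 libraries in 1 fit, 105 at 2-fold or more and 749 at an adjusted p under 0.10. Leaving out 1 library gave 143 (control replicate 4) to 343 (STZ replicate 6), and also 156 (control 1), 211 (control 3), 210 (STZ 1), 206 (STZ 3) and 151 (STZ 4). Upper quartile scaling gave 58 higher and 416 lower against 81 and 272. Against 226 in pIC, the count was 468 by DESeq2, 367 by voom, 375 with the striatal score, 72 at 2-fold or more and 385 at 0.10, and 128 (control 2) to 272 (STZ 3) with 1 library left out, with 133 (control 1) and 139 (control 4). With an estimated correlation 1 list was called in each region, and fry called 10 in PVT. List counts were 11 to 21 in PVT and 6 to 9 in pIC with 1 library left out. The interaction gave 4 genes by DESeq2, 1 with no filter, and 0 to 1 with both libraries of 1 label left out (1 without control 2, control 3 or STZ 1). The regional difference gave 7948 with no minimum fold (by construction) and 596 to 1093 with both libraries of 1 label left out. The correlation was 0.574 for genes of 10 CPM or more, and 0.283 (control 2) to 0.487 (control 4), with 0.380 (control 3) and 0.385 (STZ 1). Marker scores gave 0 calls under each alternative, in a test where a list at the smallest possible p does not pass by itself. With the ependyma score as a covariate the medians in PVT were 0.47 for choroid plexus (called in the opposite direction, adjusted p = 1.7e-04), −0.12 for postsynaptic and −0.15 for synaptic vesicle genes (neither called) and −0.70 for immediate early genes (called, adjusted p = 1.6e-05). Ifnar1 in PVT was 0.0034 with the thalamus score, 0.026 with 3 scores and −0.067 to 0.018 with 1 library left out (0.0036 without STZ 4), and Ifngr1 was −0.0053 with upper quartile scaling, none of them called. Where no construction is named, the cause was not tested.

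With the replicate number as a block, PVT had 72 genes and pIC 240, the lists 20 and 8, and Ifnar1 in PVT was 0.012. In these fits 40 of 74 named genes in PVT and 48 of 58 in pIC kept their side. Equal numbers were taken as different animals, and STZ replicates 5 and 6 have no control of that number, so this block is not part of the design. With the label shared across regions as a block, the interaction had 0 genes and the regions 785. Residuals of control and STZ libraries that share a number correlated at −0.28 to 0.459 in PVT and −0.0525 to 0.364 in pIC, and those of libraries that share a label correlated across regions at −0.118 to 0.251. Across regions 5 of 10 labels were over 0.1 and 5 of 10 matched their own label best, a hint from the data, not the design, that some labels mark 1 mouse in both regions. Against it, Fam205a3 and Fam205a4 took opposite levels across regions for control 2, control 3, STZ 2 and STZ 3, the last 2 among those that matched their own label, so the question stays open. The block was kept out of the main tests because not every pair was over 0.1.

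Over 100 library splits, chance was excluded for the pIC count (226, 1 as large, highest other 2). The PVT count (353, highest other 883) and correlation (0.451, highest other 0.462) were each reached rarely, in 2 of 100 splits. The PVT split of 883 genes (controls 1 and 4, STZ 5 and 6) points to a structure of the samples, with score differences of −0.931 for cortical excitatory and 0.352 for PVT neurons without overlap, and of 1.95 for hypothalamus, 0.942 for habenula, −0.305 for GABAergic neurons and 0.229 for oligodendrocyte precursors with overlap (exact permutation p of 0.019 to 0.0333, not adjusted). Chance was not excluded for the list counts, 16 in PVT (41 splits, highest other 24) and 6 in pIC (84 splits, highest other 24). The interaction called 0 genes, which each of 100 splits reaches by construction, so this count decided nothing (highest other 629, in the split that gave 883 in PVT). The regions (873, 35 splits) and overlap (113 genes) had a highest other of 0. Other region splits mixed PVT with pIC and other splits called at most 2 genes in pIC, so by construction neither decided anything.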

Other observations

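All genes in this part were chosen after their values were seen, and the values are given without a test of their cause. Of 13 genes of antigen processing and presentation on class I molecules, 11 were lower in the PVT of STZ mice (median −0.90) and 10 in the pIC (median −0.77), and 3 of them are also in the interferon list. B2m (ENSMUSG00000060802), the light chain of class I molecules, fell by 0.95 in PVT (SE 0.0982, edgeR adjusted p = 4.8e-04, n = 4 control and 6 STZ libraries), from 206 ± 34.1 to 107 ± 7.57 CPM, and by 0.77 in pIC (SE 0.0788, adjusted p = 1.0e-04). Tap1 (ENSMUSG00000037321), which carries peptides into the endoplasmic reticulum, fell by 1.49 in PVT (SE 0.139, adjusted p = 2.6e-04) and by 1.5 in pIC (SE 0.132, adjusted p = 2.3e-05). The immunoproteasome subunit Psmb8 fell by 1.29 in PVT (SE 0.132, adjusted p = 4.8e-04) and by 1.19 in pIC (SE 0.174, adjusted p = 0.00218). Without the 4 PVT libraries lowest in thalamus genes the adjusted p in PVT was 0.0605 for Tap1 and 0.099 for Psmb8. Of interferon-induced GTPases 14 of 15 were lower in PVT (median −1.90) and 13 of 14 in pIC (median −1.31), with near-identical copies among them.

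The interferon receptor genes Ifnar1, Ifnar2 and Ifngr1 had log2 fold changes of −0.31 to 0.14, and their difference from the genes above was not tested. Ifnar1, a chain of the type I receptor, had a log2 fold change of −0.03 in PVT (SE 0.0768, edgeR adjusted p = 0.896) and −0.20 in pIC (SE 0.0605, adjusted p = 0.148). Ifnar2 had −0.31 in both, with an adjusted p of 0.123 in PVT and 0.0301 in pIC, where it was 0.0557 without control replicate 2 and 0.114 without control replicate 4. Ifngr1, a chain of the interferon gamma receptor, had 0.05 in PVT (adjusted p = 0.771) and 0.14 in pIC (adjusted p = 0.556). Irf9, a transcription factor of the interferon response, fell by 1.54 in PVT (SE 0.142, adjusted p = 2.3e-04) and by 1.5 in pIC (SE 0.111, adjusted p = 3.9e-06).

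Hypothalamic peptide transcripts varied widely among PVT libraries of both treatments. Oxytocin (Oxt) ran from 0.127 CPM in STZ replicate 1 to 159 CPM in STZ replicate 6, and vasopressin (Avp) from 0.0843 CPM to 352 CPM in STZ replicate 5. Melanin-concentrating hormone (Pmch) was 329 CPM in STZ replicate 5 and 142 CPM in STZ replicate 6, and at most 0.854 CPM in PVT control libraries.

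Fam205a3 and Fam205a4, near-identical copies, took opposite levels in single libraries of both regions and both treatments. Fam205a4 was 22.7 CPM and Fam205a3 0 CPM in PVT control replicate 2, against 0.311 and 12.6 CPM in PVT control replicate 4. The libraries with the same label did not always match across regions. In pIC control replicate 2 Fam205a4 was 0.778 CPM and Fam205a3 30.6 CPM, the opposite of the PVT library with that label, and PVT and pIC STZ replicate 3 differed in the same way (Fam205a4 3.01 and 22.4 CPM, Fam205a3 16.7 and 0.0393 CPM). So did control replicate 3 (Fam205a4 1.45 and 22.9 CPM, Fam205a3 19.6 and 6.28 CPM) and STZ replicate 2 (Fam205a4 25.5 and 1.04 CPM, Fam205a3 0.142 and 32.2 CPM).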
